A study of Mus musculus with 12 samples.

How the data were processed

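RNA sequencing was analysed from 6 libraries of the mouse embryonic stem cell line E14, derived from a male embryo. The cells were grown in medium with serum, LIF and a pair of kinase inhibitors known as 2i, per the labels' protocols. The labels assign 2 libraries to wild type (WT), 2 to clone 1 and 2 to clone 2 of a Bcat1 knockout. A further 6 samples of a time course were not analysed here. Total RNA was depleted of ribosomal RNA before library construction, per the labels' protocols. The deposited values are counts of reads per gene, whole numbers that were not normalised. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1 and the build mm10, without giving their roles. The annotation, strand setting and filters of the counting are not given in the sources used here. Because the strand setting is unknown, overlapping or antisense genes cannot be separated. Reads of near-identical gene copies can align to several places, so they may be split or lost.

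Each deposited count file held 52535 gene entries and 5 HTSeq summary entries, which stayed out of library sizes and tests. As a share of all reads in a library, reads without a feature made up 4.14% to 5.35%, ambiguous reads 6.96% to 9.10%, reads of low alignment quality 6.00% to 7.30%, unaligned reads 2.44% to 3.09% and reads with several alignments 15.6% to 16.6%. Reads from mitochondrial genes made up 1.95% to 2.31% of gene counts, and the 10 most abundant genes 4.95% to 5.38%. Of 26926 genes with any count, 14946 passed edgeR's filterByExpr on groups. Coordinates come from GENCODE M21 on GRCm38, the assembly of mm10, and 14549 tested genes had a single position there. Within each group the counts of both libraries differed by more than sampling noise, with a chi-square per gene of 3.57 in WT, 8.79 in clone 1 and 3.27 in clone 2 over genes with at least 10 counts.

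Tests used edgeR 4.0.16 with TMM normalisation, the quasi-likelihood F test, and Benjamini-Hochberg adjustment at 0.05 in R 4.3.3, two-sided. The libraries labelled knockout were compared with WT as 1 genotype, so that the difference between clones entered the spread. That fit still counts 4 libraries from 2 clones as independent, so its p-values may be too small. The clone contrasts came from a fit of 3 groups. Gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, over lists with 5 or more measured members, with an estimated correlation and fry beside it. The groups, the main tests, the 25 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The exception leaves out the chromosome stretches and chromosome Y, and some tests of explanations were chosen later too. The rule named Bcat1 and Bcat2. It added the 8 largest rises and 8 largest falls among called genes of mean CPM of 1 or more that were on 1 side in all libraries, 5 and 5 between clones, and up to 4 members of each list with the smallest p. Among the largest rises and falls, listed symbol patterns of predicted genes (such as Gm or Rik), pseudogenes and small or ribosomal RNAs were passed over. Clone-based symbols such as CT010575.2 match none of these patterns, and list members were not passed over. A gene that the rule takes is not reported here. In a group with 0 counts the floor was 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% counting interval was given. Overlap of the clone contrasts with no gene changed came from 20 simulations, and chance runs along chromosomes from 100 permutations of gene order.

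The fits were tested on simulated counts with known changes. All libraries were drawn independently, with the same spread in every group and no effect shared by the libraries of a clone. The rates therefore do not cover libraries that depend on each other within a clone, or a wider spread in clone 1. For the genotype comparison over 14564 genes, 31.3% of genes planted at a log2 change of 0.59, 65.7% at 1 and 86.4% at 2 were recovered, with 3.94% false calls over all sizes. For clone 1 over 14577 genes the values were 56.7%, 80.6%, 93.9% and 3.75%. For clone 2 over 14565 genes they were 52.2%, 83.6%, 98.5% and 4.88%, and those between the clones over 14585 genes were 52.2%, 71.6%, 97.0% and 6.37%. Alternatives were DESeq2 1.42.0, other size factors, other filters, a minimum fold, a replicate block, a fit of only the 4 libraries compared, the mean of both clone contrasts, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9. The scan for neighbouring genes used a running median over 15 genes of mean CPM of 5 or more, a minimum of 0.4 on the log2 scale and a run of at least 15 genes. These settings were chosen after a look at the data. Log2 CPM values used a prior count of 2.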

Results

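The data were gene counts from 6 libraries of E14 mouse embryonic stem cells, 2 each from wild type (WT) and from 2 clones labelled as Bcat1 knockout. Bcat1 encodes a cytosolic transaminase that starts the breakdown of branched-chain amino acids, and the series title ties it to self-renewal, pluripotency and Ras signalling. Gene counts totalled 13294805 and 13923262 in WT, 12116149 and 12618319 in clone 1, and 11976149 and 12864573 in clone 2. Log2 CPM values correlated across genes at 0.987 to 0.989 within groups and at 0.967 to 0.975 between groups. The first principal component held 43.3% of the variance and separated WT from the libraries labelled knockout, and the second held 31.8% and separated the clones. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only.

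Bcat1 RNA showed no difference between genotypes that passed the test. Bcat1 (chromosome 6, 144993835 to 145076184, GRCm38) stood at 608 ± 8.35 CPM (SD, n = 2) in WT, 639 ± 31.9 in clone 1 and 581 ± 2.38 in clone 2. The log2 fold change was 0.01 ± 0.08 (SE), with an adjusted p of 0.977, and it lay between -0.04 and 0.03 with each library left out. Bcat2, the mitochondrial enzyme of the same reaction, had a log2 fold change of 0.06 ± 0.10 and an adjusted p of 0.790. The RNA level thus gives no sign of the knockout, and does not speak against the label either. Gene counts do not check a knockout that leaves the transcript in place, as a small insertion or deletion can. The clones are called the libraries labelled knockout throughout, and every direction given here rests on that label.

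Across the libraries labelled knockout, the largest rises by the naming rule included the germ cell genes Tuba3b and Sohlh2, and the largest fall was that of Cdx2, a homeobox factor required for trophectoderm. Tuba3b, a testis alpha-tubulin (chromosome 6, 145615757 to 145621479), had 0 counts in WT and 100 in the libraries labelled knockout, at least 17.6-fold higher by the floor over the group. Its near-identical copy Tuba3a rose by 4.62 ± 0.32 (log2, SE), though reads of such copies are hard to assign. Sohlh2, a transcription factor of germ cells, rose by 5.65 ± 0.77, Dnajc5g, a DnaJ-domain protein, by 5.07 ± 0.59, the cation channel gene Pkd2l1 by 4.87 ± 0.34 and Igfbp7, a secreted growth factor binding protein, by 4.44 ± 0.63. CT010575.2, which has no position in the annotation used, went from 1 to 88 counts, a ratio of 46.5 with a counting interval of 8.13 to 1858. Rhox13, an X-linked homeobox gene of the germline, went from 2 to 95 counts, a ratio of 25.1 (6.76 to 210). Cdx2 fell by 2.92 ± 0.40, Ptgs1, a prostaglandin-producing cyclooxygenase, by 2.87 ± 0.47, Enox1 by 2.66 ± 0.38, Abcc12, an ABC transporter, by 2.46 ± 0.38 and Nt5e, a cell surface enzyme that makes adenosine, by 2.39 ± 0.25. The metal importer gene Slc39a14 fell by 2.29 ± 0.44, the lipase gene Mgll by 2.29 ± 0.52 and Aldh3a1, an aldehyde dehydrogenase, by 2.25 ± 0.36. The adjusted p was 0.0392 or less for each of these genes.

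Of 14946 genes tested, 951 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 635 higher and 316 lower in the libraries labelled knockout. The 4 libraries labelled knockout come from 2 clones, so they are not 4 independent replicates. Leaving out either WT library leaves 1 in that group. A call lost that way can come from lower power and need not mean that the WT libraries disagree. The count rests on both WT libraries, since it was 79 without WT replicate 1 and 99 without WT replicate 2, and it was 1752 with no filter beyond 1 count and 3226 for the mean of the clone contrasts. Among the 65 called genes that the naming rule takes, 54 lost their call without WT replicate 1 and 51 without WT replicate 2, and 10 kept it under all alternatives, Tuba3b, Dnajc5g, Pkd2l1, Tuba3a, Nt5e, Sall2, Cdkn2a, Mest, Grb10 and Dazl. The highest adjusted p over all alternatives was 0.0915 for Sohlh2, 0.0833 for Cdx2, 0.204 for Slc39a14 and 0.289 for Mgll. For CT010575.2 it was 0.317, and that call was also lost without clone 1 replicate 1 (0.0527) or clone 1 replicate 2 (0.0644).

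**Figure D1:**
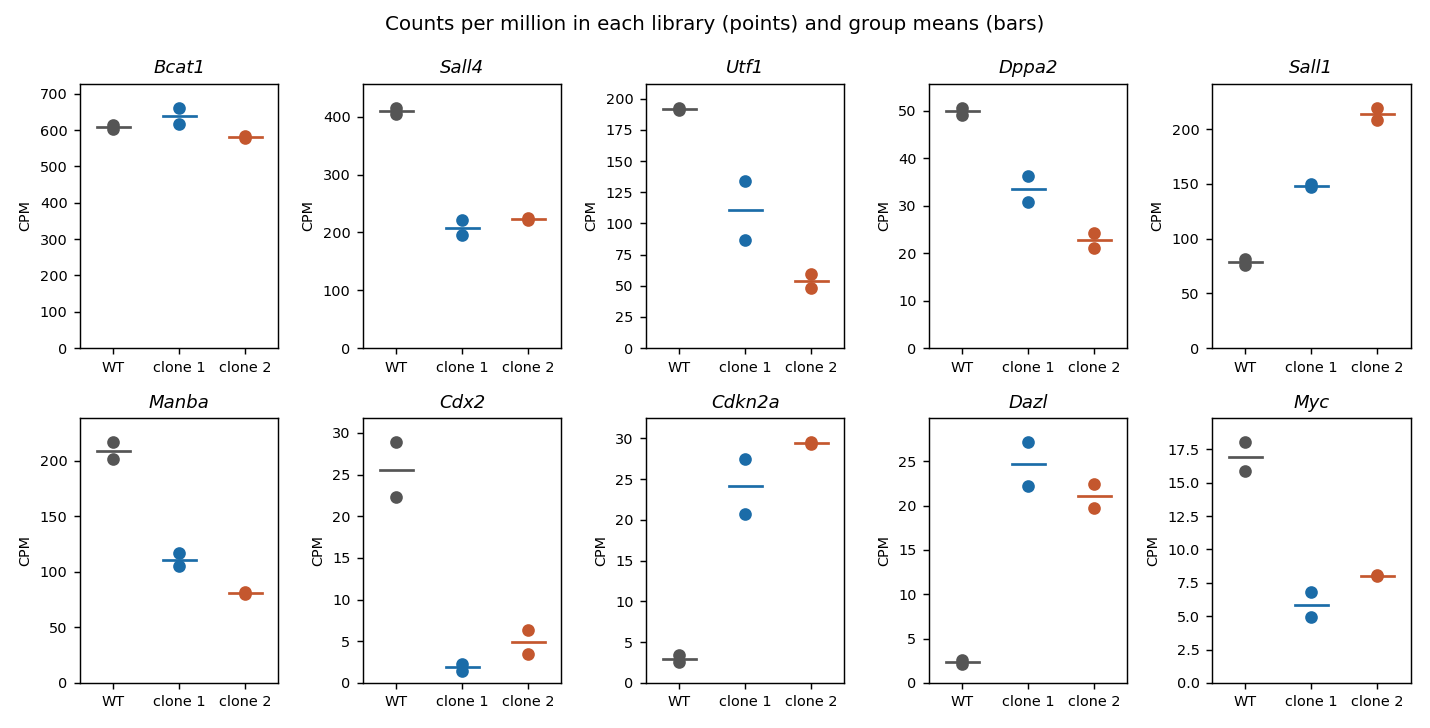
CPM values (y axis) of 10 genes in each library of WT, clone 1 and clone 2 (points), with the group mean (bars) and the axis starting at 0. Bcat1 sits between 579 and 662 in all libraries, Sall4 near 410 in WT and at 225 or less in both clones, and Cdx2 at 22.3 or more in WT and at 6.33 or less in the clones.

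Among core and naive pluripotency genes more fell than rose, although most were not called. Sall4, a zinc finger factor of the core network, fell by 0.93 ± 0.08 from 410 ± 7.65 CPM (SD, n = 2) in WT to 216 ± 13.5 (n = 4), with an adjusted p of 4.19e-04, and it lies in a stretch of chromosome 2 that was lower in both clones. Dppa2, a chromatin-associated factor of early development, fell by 0.83 ± 0.18, while Sall1 rose by 1.20 ± 0.18. Of the 12 core pluripotency factors, 1 rose, 4 fell and 7 were not called, and adjusted over the list alone 1 rose and 6 fell. Camera placed the list lower with an adjusted p of 0.00102, but with adjusted p = 0.234 with an estimated correlation (range over alternatives 1.11e-04 to 0.234). In the naive pluripotency list of 18 genes, 3 fell, Manba by 1.12 ± 0.14, Tdh, a threonine dehydrogenase active in mouse stem cells, by 0.47 ± 0.08 and Tbx3 by 0.41 ± 0.09, and 15 were not called. With p adjusted over the list alone 7 fell, and camera gave an adjusted p of 0.00132, with adjusted p = 0.234 with an estimated correlation (range 4.19e-04 to 0.234). Klf2 had a log2 fold change of -0.53 ± 0.15 and was not called. Without WT replicate 1 the calls of Sall1, Dppa2, Manba, Tdh and Tbx3 were lost, with a highest adjusted p over alternatives of 0.108, 0.255, 0.0703, 0.156 and 0.282; without WT replicate 2 all of these but Manba were lost too. Tbx3 also lost its call without clone 2 replicate 1 (0.0579).

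Formative and primed genes went both ways. Sall2, a zinc finger factor, rose by 1.69 ± 0.19 and Sox4 by 2.02 ± 0.38, while Tcf15 fell by 0.70 ± 0.17. Of 17 measured, 2 rose, 1 fell and 14 were not called, and adjusted over the list alone 4 rose and 1 fell, with a camera adjusted p of 0.177. Without WT replicate 1 or WT replicate 2 the calls of Sox4 and Tcf15 were lost, with a highest adjusted p over alternatives of 0.209 and 0.320, and Tcf15 lost it without clone 2 replicate 1 too (0.0723).

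The two-cell-like state had 3 measured genes and none was called for genotype. Zscan4c was at 0 counts in WT and 25 in the libraries labelled knockout, at least 4.40-fold higher, and Zscan4d went from 1 to 22, a ratio of 11.6 (1.88 to 480), in a gene family with near-identical copies. Most of these counts came from clone 1, with 21 against 4 in clone 2 for Zscan4c and 20 against 2 for Zscan4d. Against WT, Zscan4c was at least 7.23-fold higher in clone 1 and at least 1.44-fold in clone 2. All 3 measured genes were called higher in clone 1 and 0 in clone 2. Between the clones 2 of the 3 were called lower in clone 2, and 3 adjusted over the list alone. These were Zscan4d, higher in clone 1 by a ratio of 9.55 (2.32 to 84.3), and Gm8300, by a ratio of 35.3 (5.96 to 1433). The Zscan4d call was lost without WT replicate 1 (0.0705), WT replicate 2 (0.0668), clone 2 replicate 1 (0.230) or clone 2 replicate 2 (0.260), and that of Gm8300 without clone 2 replicate 1 (0.0622).

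Markers of differentiated lineages moved in few genes. Trophoblast genes fell in 3 of 10, Cdx2, Gata2 by 1.99 ± 0.26 and Tead4 by 0.40 ± 0.09, and 7 were not called. The count adjusted over the list alone was also 3. Camera did not call the list (adjusted p = 0.0737), although the adjusted p was 0.0364 without WT replicate 2, 0.0423 without clone 1 replicate 2, 0.0453 without clone 2 replicate 1 and 0.0227 by fry, over a range of 0.0227 to 0.282. Among 8 ectoderm and neural genes, Nefl, a neurofilament subunit, rose by 1.82 ± 0.27 and Sox21 by 2.32 ± 0.37 and 6 were not called, with 3 higher adjusted over the list alone. The camera adjusted p was 0.194, while fry gave 0.00816 and the mean of the clone contrasts 4.64e-04 (range 4.64e-04 to 0.418). The list median was -0.06, its mean 0.78 and its test direction higher. Mesoderm and primitive streak genes had 1 rise among 10, Kdr, a VEGF receptor, (adjusted p = 0.00479), and 9 not called. Adjusted over the list alone 1 rose and 2 fell, with a camera adjusted p of 0.818. Primitive and definitive endoderm genes had 1 fall among 13, Hnf4a, a hepatic transcription factor, by 1.68 ± 0.43, and 12 not called. There were 2 rises and 1 fall adjusted over the list alone, with a camera adjusted p of 0.588. Markers of fibroblasts and feeder cells, another cell type a stem cell culture can hold, had 1 rise among 9 and 8 not called. It was Col1a2, a collagen gene, at 1 count in WT and 66 in the libraries labelled knockout, a ratio of 34.9 (6.05 to 1399). Fn1, which stem cells express too and which was named after its values were seen, had 2419 CPM or more in all libraries and was not called. The camera adjusted p was 0.109, with 2 higher adjusted over the list alone. Without WT replicate 1, the calls of Gata2, Tead4, Nefl, Sox21, Kdr, Hnf4a and Col1a2 were lost, with highest adjusted p over alternatives of 0.0786, 0.260, 0.115, 0.130, 0.102, 0.294 and 0.164; without WT replicate 2 all of these but Gata2 were lost. Hnf4a also lost its call without clone 2 replicate 1 (0.0533), and Tead4 without clone 2 replicate 1 (0.0534) or clone 2 replicate 2 (0.0617).

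Among target genes of ERK and FGF signalling, which the title's Ras pathway feeds, 5 of 23 fell and 1 rose. All libraries came from cells grown with the kinase inhibitors of 2i, and activity of the pathway was not measured. Myc, a growth-promoting transcription factor, fell by 1.28 ± 0.21, Spry4, a feedback inhibitor of receptor kinases, by 0.85 ± 0.16 and Epha4, an ephrin receptor, by 0.56 ± 0.10, while Etv4, an ETS factor, rose by 0.61 ± 0.14. Of 23 measured, 1 rose, 5 fell and 17 were not called, with the same counts adjusted over the list alone. Camera called the list lower (adjusted p = 0.0170), with adjusted p = 0.0549 without WT replicate 2 and adjusted p = 0.234 with an estimated correlation (range 0.00459 to 0.234). Genes of the Ras family and of Ras-MAPK components had 4 rises and 0 falls among 33, with 29 not called. They were Rasal1, a GTPase-activating protein that turns Ras off, by 1.41 ± 0.18, Sos2 by 1.33 ± 0.23 and Sos1 by 0.41 ± 0.10, both exchange factors that turn Ras on, and Mras, a Ras-family GTPase, by 0.96 ± 0.14. The count was the same adjusted over the list alone, and camera did not call the list (adjusted p = 0.109), while fry gave 0.00816 (range 0.00816 to 0.282). Branched-chain amino acid catabolism held 1 rise among 24, Pcca, a propionyl-CoA carboxylase subunit, by 0.50 ± 0.11, and 23 not called, with the same count adjusted over the list alone and a camera adjusted p of 0.952. The list median was 0.04 while the test direction was lower. Without WT replicate 1 or WT replicate 2 the calls of Myc, Epha4, Spry4, Etv4, Rasal1, Mras, Sos2, Sos1 and Pcca were lost, with highest adjusted p over alternatives between 0.0770 for Rasal1 and 0.359 for Sos1. Without clone 2 replicate 1 or clone 2 replicate 2 the calls of Etv4 (0.0513 and 0.0521), Sos1 (0.0812 and 0.0654) and Pcca (0.0551 and 0.0537) were lost as well.

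Of 18 germline genes measured, 6 rose. Dazl, an RNA-binding protein of germ cells, went from 2.38 ± 0.340 CPM (SD, n = 2) to 22.9 ± 3.08 (n = 4), a log2 change of 3.26 ± 0.21 (adjusted p = 1.60e-04), and Hormad1, a meiotic chromosome axis protein, rose by 1.97 ± 0.28. The other 12 were not called and 0 fell, and adjusted over the list alone 8 rose. Camera gave an adjusted p of 2.67e-10, with adjusted p = 0.234 with an estimated correlation (range 2.25e-13 to 0.234). Extracellular matrix and adhesion genes had 3 rises among 22, Cdh1, the epithelial cadherin, by 0.53 ± 0.08, Itga5 by 0.36 ± 0.08 and Itgb1 by 0.60 ± 0.14, both integrins, against 1 fall, Vim, an intermediate filament protein, by 0.35 ± 0.08, and 18 were not called. There were 7 rises and 1 fall adjusted over the list alone, with camera adjusted p = 0.0126 and adjusted p = 0.234 with an estimated correlation (range 0.00131 to 0.234). Cell cycle genes had 1 rise, E2f1 by 0.39 ± 0.09, and 1 fall, Rrm2, a subunit of ribonucleotide reductase, by 0.44 ± 0.07, among 26, with 24 not called, and adjusted over the list alone 1 rose and 5 fell. Camera called that list lower (adjusted p = 0.0126), with adjusted p = 0.0539 without WT replicate 1, 0.0529 by fry and adjusted p = 0.418 with an estimated correlation (range 0.00469 to 0.418). Without WT replicate 1 or WT replicate 2 the calls of Hormad1, Cdh1, Itga5, Itgb1, Vim, E2f1 and Rrm2 were lost, with highest adjusted p over alternatives of 0.0960, 0.146, 0.281, 0.352, 0.255, 0.327 and 0.154. Without clone 2 replicate 1 the calls of Itga5 (0.0748), Vim (0.0655) and E2f1 (0.0637) were lost too, as were those of Itga5 (0.0694) and E2f1 (0.0608) without clone 2 replicate 2 and of Itgb1 (0.0657) without clone 1 replicate 2. In all, camera called 6 of 24 lists, 0 of which passed with an estimated correlation, while fry called 8.

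Each clone was also compared with WT on its own, in a fit whose spread is that within groups. Counts from this fit are not comparable with the 951 of the genotype fit, since the mean of both clone contrasts gave 3226 here. Clone 1 had 3280 called genes, 1856 higher and 1424 lower, and clone 2 had 2674, 1507 higher and 1167 lower. The order was turned in fits of only the 4 libraries compared, with 2795 for clone 1 and 4065 for clone 2. These counts therefore do not show which clone changed more. Both clones raised Cdkn2a, a cell cycle inhibitor, which stood at 2.95 ± 0.625 CPM (SD, n = 2) in WT, 24.1 ± 4.73 in clone 1 and 29.4 ± 0.139 in clone 2, and Cdx2 fell by 3.76 ± 0.28 in clone 1 and fell by 2.39 ± 0.24 in clone 2. In germline genes, 12 of 18 were higher in clone 1, and 7 higher and 1 lower in clone 2. Naive pluripotency genes fell in 9 of 18 in clone 1, and in clone 2 rose in 2 and fell in 6. In clone 1 the count was 1576 without WT replicate 1, 1687 without WT replicate 2 and 2163 by DESeq2. In clone 2 it was 1165 without WT replicate 1, 1317 without WT replicate 2, 4168 without clone 1 replicate 1, 4191 without clone 1 replicate 2, 1332 and 1485 without clone 2 replicate 1 and 2, 4065 in a fit of the 4 libraries compared and 1777 by DESeq2.

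Both clones shared 862 genes that were higher and 493 that were lower, 1355 in all, against 187 and 111 for independent lists of these sizes. The shared count was 594 without WT replicate 1, 656 without WT replicate 2, 765 without clone 2 replicate 1, 862 without clone 2 replicate 2 and 869 by DESeq2. Another 60 genes were called in opposite directions. In simulations with every group drawn around the WT means, both clones shared at most 1 gene, 0.05 on average over 20 simulations. With no gene changed, few genes are called at all. That count therefore does not measure how far shared controls make the called genes of both clones overlap. Log2 fold changes of both clones correlated across genes, which are not independent replicates, at 0.640 against 0.491 in simulation, and 70.5% had the same sign against 66.6%. Their covariance was 0.341 against 0.0338, a difference of 0.307. The WT libraries are too few to split, so part of the excess may come from the shared controls. Differences from WT that both clones carry for other reasons, such as a shared ancestor, cannot be told apart from the genotype here.

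Between the clones, most genes listed for the ATF4 response to amino acid shortage were higher in clone 2. Neither ATF4 activity nor amino acid levels were measured. Pck2, a mitochondrial gluconeogenic enzyme, stood at 201 ± 7.43 CPM (SD, n = 2) in WT, 87.6 ± 6.99 in clone 1 and 228 ± 6.42 in clone 2, a log2 difference of 1.38 ± 0.09 between clones. Atf5, a stress transcription factor, differed by 1.83 ± 0.13, Gpt2, an alanine transaminase, by 1.01 ± 0.08 and Psat1, an enzyme of serine synthesis, by 0.89 ± 0.08. Of 26 list members, 21 were higher in clone 2, 0 lower and 5 not called, and adjusted over the list alone 24 were higher and 1 lower. The median difference was 0.84. Camera gave an adjusted p of 6.41e-35, and adjusted p = 0.0475 with an estimated correlation (range 1.04e-38 to 0.0475). Against WT, 15 members were lower and 1 higher in clone 1 (median -0.47), and 14 higher and 3 lower in clone 2 (median 0.35). In the genotype comparison 0 rose and 1 fell, Cebpb, by 1.47 ± 0.28, which lies in the lower stretch of chromosome 2, and the camera adjusted p was 0.571, with 3 lower adjusted over the list alone, a median of 0.01, a mean of -0.01 and a test direction of lower. The Cebpb call was lost without WT replicate 1 or WT replicate 2, with a highest adjusted p over alternatives of 0.217.

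**Figure D2:**
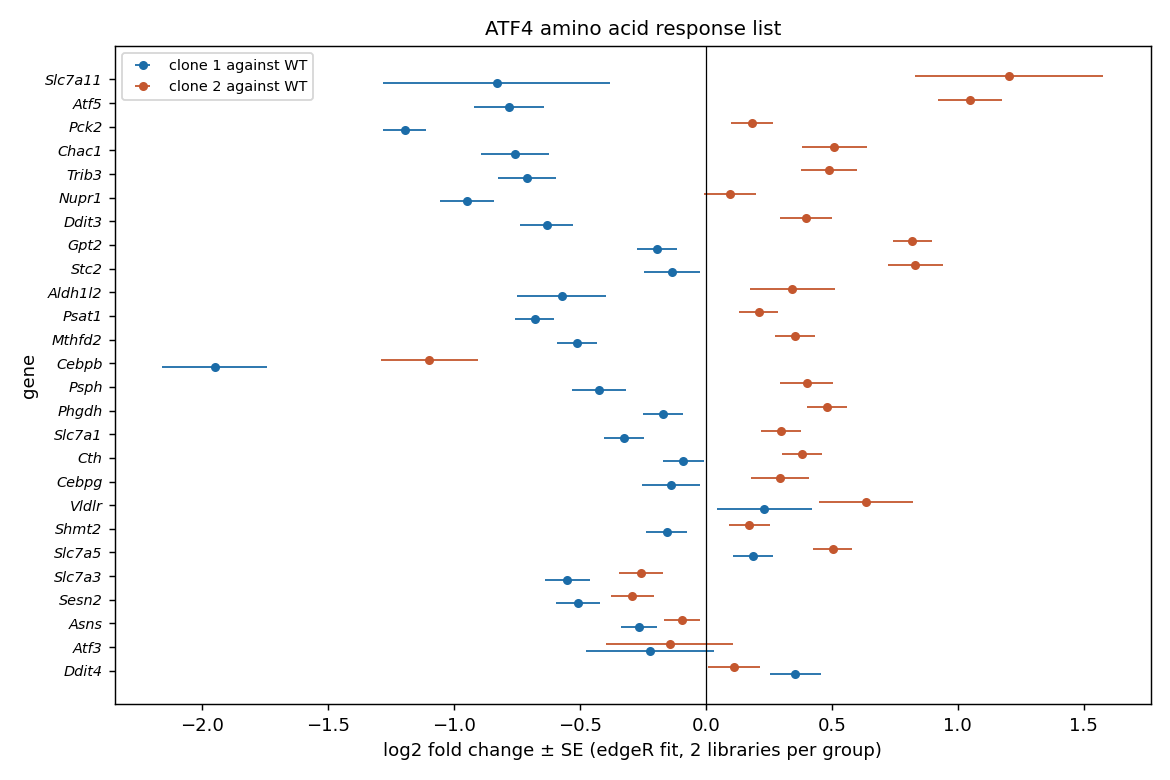
Log2 fold change against WT (x axis, points) with its standard error (bars) for each of 26 genes of the ATF4 list (y axis), in clone 1 and clone 2. Most points of clone 1 sit left of 0 and most of clone 2 right of it, with medians of -0.47 and 0.35.

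Single genes set the clones apart by more. Uba1y, a Y-linked ubiquitin-activating enzyme gene, had 196 counts in clone 2 and 0 in clone 1, at least 68.4-fold higher. Uty, also Y-linked, had 353 against 1, a ratio of 370 (65.9 to 14644). Eif2s3y, a Y-linked translation factor gene, was higher by 8.18 ± 0.31 and Ddx3y, a Y-linked RNA helicase gene, by 7.84 ± 0.39. Over 5 protein-coding Y-linked genes, counts totalled 2725 in clone 2, 46 in WT and 9 in clone 1. Y-linked RNA was thus near-absent in WT and clone 1 although E14 is of male origin, and the labels give no reason for it. Values of clone 2 against WT or clone 1 compare cells that also differ in Y-linked RNA. Wnt10b, a secreted Wnt ligand on chromosome 15, was higher by 7.18 ± 0.27, at 52.3 ± 3.46 CPM (SD, n = 2) in clone 2. Lower in clone 2 were Zan at 3 counts against 46, a ratio of 14.6 (4.71 to 73.6) in favour of clone 1, Slfn5 by -3.55 ± 0.52, Atp2b2, a calcium pump, by -3.41 ± 0.35, Rhobtb1 by -3.38 ± 0.60 and Fer1l4 by -3.27 ± 0.54. Over all genes, 2141 differed, 989 higher and 1152 lower in clone 2, with 974 without clone 2 replicate 1, 1006 without clone 2 replicate 2 and 1358 by DESeq2.

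Further lists differed between the clones by camera, and each of them had its call lost with an estimated correlation. Amino acid transport and mTORC1 sensing genes were higher in 7 and lower in 1 of 18, led by the glutamine transporter gene Slc38a2 (0.80 ± 0.08) and Slc1a5 (0.50 ± 0.08), with adjusted p = 0.00182 and adjusted p = 0.228 with an estimated correlation (range 5.21e-04 to 0.228). LIF and STAT3 targets were higher in 6 of 14, including Klf5 (0.51 ± 0.10) and Pim1 (1.22 ± 0.16), which lies in the chromosome 17 stretch that was lower in clone 1, with adjusted p = 0.00239, 0.0706 by fry and adjusted p = 0.228 with an estimated correlation (range 1.99e-06 to 0.228). Imprinted genes were higher in 8 and lower in 2 of 21, such as Peg10 (1.47 ± 0.11) against Phlda2 (-2.79 ± 0.24), with adjusted p = 0.00590 and adjusted p = 0.228 with an estimated correlation (range 0.00404 to 0.228). Naive pluripotency genes were higher in 5 and lower in 2 of 18, among them Nr0b1 (0.70 ± 0.10), with adjusted p = 0.0497, 0.143 without clone 1 replicate 1, 0.0548 without clone 2 replicate 2 and adjusted p = 0.228 with an estimated correlation (range 0.0198 to 0.228). Adjusted over the list alone, these counts were 8 and 1, 7 and 0, 10 and 3, and 6 and 2.

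Camera called other lists lower in clone 2. Germline genes were lower in 6 of 18, among them Ddx4 (-1.39 ± 0.24), Tex101 (-1.95 ± 0.35) and Tuba3a (-0.73 ± 0.10), with adjusted p = 9.39e-05 and adjusted p = 0.228 with an estimated correlation (range 3.65e-05 to 0.228). Glycolysis and hypoxia genes were lower in 8 of 26, such as the lactate exporter gene Slc16a3 (-0.61 ± 0.08) and Eno3 (-1.67 ± 0.15), with adjusted p = 1.22e-04 and adjusted p = 0.328 with an estimated correlation (range 1.99e-06 to 0.328). Endoderm genes were higher in 1 and lower in 5 of 13, led by the collagen gene Col4a1 (-2.61 ± 0.18), with adjusted p = 0.00239 and adjusted p = 0.228 with an estimated correlation (range 8.55e-04 to 0.228). Formative genes were higher in 1 and lower in 8 of 17, among them the DNA methyltransferase gene Dnmt3a (-0.97 ± 0.11) and its partner Dnmt3l (-0.97 ± 0.08), with adjusted p = 0.0176, 0.0660 without clone 1 replicate 2 and adjusted p = 0.228 with an estimated correlation (range 0.00288 to 0.228). Adjusted over the list alone, lower members numbered 10 for germline, 9 for glycolysis, 6 for endoderm and 8 for formative genes. Ectoderm genes, called higher with adjusted p = 0.00685, were higher in 3 and lower in 1 of 8, adjusted over the list alone too. The adjusted p was 0.0750 without clone 1 replicate 1, 0.154 without clone 1 replicate 2 and adjusted p = 0.228 with an estimated correlation (range 0.00338 to 0.228), and the median was -0.06 against a mean of 0.31. Fibroblast genes (2 of 9 lower, adjusted p = 0.0497, adjusted p = 0.259 with an estimated correlation, range 0.0157 to 0.259) and cholesterol synthesis genes (4 of 20 lower, adjusted p = 0.0497, adjusted p = 0.228 with an estimated correlation, range 0.0204 to 0.228) were called less firmly. The adjusted p was 0.133 without clone 1 replicate 1, 0.0743 without clone 1 replicate 2, 0.0501 without clone 2 replicate 1 and 0.0726 without clone 2 replicate 2 for the former. It was 0.0707, 0.0688, 0.0776, 0.0501 and 0.136 without WT replicate 1, WT replicate 2, clone 1 replicate 1, clone 2 replicate 1 and clone 2 replicate 2 for the latter. Adjusted over the list alone 3 and 4 were lower.

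Whole chromosomes changed little. Median log2 differences from WT over the tested genes of each autosome and X lay between -0.07, for chromosome 1 in clone 2, and 0.06, and mitochondrial genes had medians of -0.11 and -0.19. Runs of neighbouring genes changed more. A stretch of chromosome 2 was lower in both clones, from 166906040 to 172382448 in clone 1 (28 genes, median -0.92) and from 166805588 to 172370535 in clone 2 (28 genes, median -0.81), and it holds Sall4 and Cebpb, with Aurka at its edge. A stretch of chromosome 17 from 28970880 to 33849774 was lower in clone 1 only among the clones (57 genes, median -0.93), with a median of -0.02 in clone 2, and it holds Pim1 and Cdkn1a. Over 10454 genes scanned, the longest run in 100 permuted gene orders was 11 genes in clone 1 and 9 in clone 2.

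**Figure D3:**
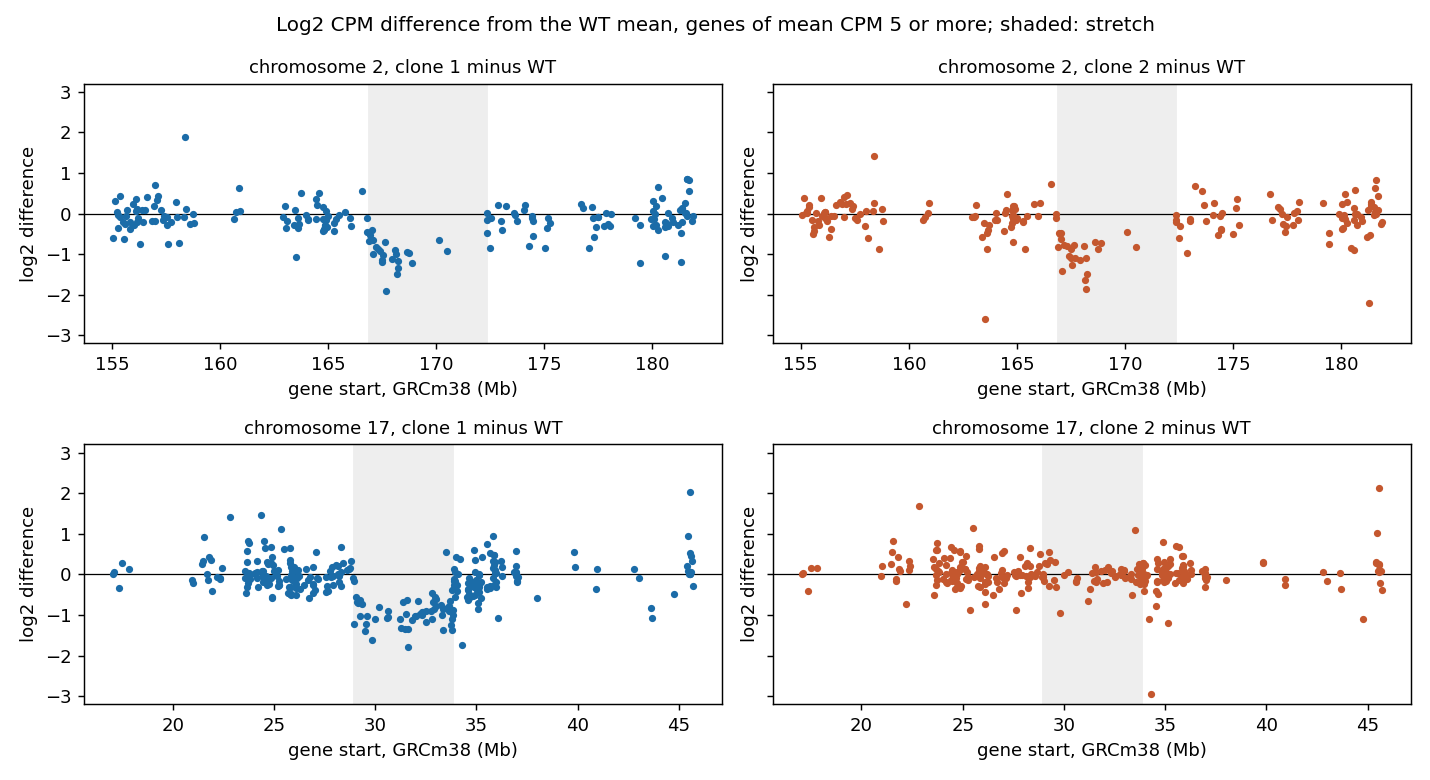
Log2 CPM difference from the WT mean (y axis) by gene start in megabases on GRCm38 (x axis) for genes of mean CPM of 5 or more, with clone 1 on the left and clone 2 on the right. The shaded stretch of chromosome 2, the part common to both clones, lies below 0 in both (medians -0.92 and -0.82), and that of chromosome 17 only in clone 1 (medians -0.93 and -0.02).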

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

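The tests of chance order of genes, and of the Bcat1 genotype as the origin of the chromosome 17 stretch or of the ATF4 difference, were chosen after the results were seen.

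A stretch of chromosome 2 was lower in both clones and a stretch of chromosome 17 in clone 1. A correction for GC content and length left medians of -0.851 on chromosome 2 in clone 2 and -1.05 on chromosome 17 in clone 1, and permuted gene orders gave runs of at most 11 genes, which argues against either as the whole cause. On chromosome 17 clone 2 had a median of -0.0170, so the fall there was not shared by both clones. The scan had already found that stretch in clone 1 only, so this is no separate test of a direct effect of the Bcat1 genotype. Such an effect would be shared only if both clones carry the same change in Bcat1, which was not checked. A lower copy number predicts that genes too low for the scan fall as well: 17 such genes on chromosome 17 had a median of -0.549, in line with it, and the 10 on chromosome 2 had -0.843 in clone 2 (8 of 10 below 0), in line with it too, but -0.445 in clone 1 (6 of 10 below 0), between both bounds set in advance. For chromosome 2 in clone 1 the prediction was therefore left undecided, with so few low genes. Any cause that acts over a whole stretch predicts the same fall of its low genes. In either clone these medians thus cannot tell a lower copy number apart from such causes. A shared ancestor of the clones may be involved, which was not tested. Values are differences from the WT libraries, so more copies of the chromosome 2 stretch in WT would look like fewer in both clones.

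The ATF4 list differed between the clones by a median of 0.839, a difference tested directly between the groups. The corrected median was 0.904, and with each library left out it was 0.701 or more, so GC content, length or a single library is not its whole cause. A direct effect of the Bcat1 genotype alone predicts 1 sign in both clones, whereas clone 1 had -0.467 and clone 2 0.348 against WT. That prediction assumes the same change in Bcat1 in both clones, which was not checked. A difference between clones in how they were grown or in nutrient supply at harvest may be involved, and was not tested.

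In the germline list 6 of 18 genes rose in the libraries labelled knockout, a pattern that could come from reads shared between near-identical tubulin copies. Without Tuba3a and Tuba3b the list of 16 genes was still called higher by camera (adjusted p = 6.11e-05, range for the whole list 2.25e-13 to 0.234, with adjusted p = 0.234 with an estimated correlation for the whole list), which argues against that as the whole cause. A biological explanation remains a hypothesis, since the estimated correlation does not call the list and replicates within a clone share their ancestry.

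Genes with opposite calls against WT in the clones that also differed between the clones numbered 60. Among the named genes, the log2 difference of clone 2 from clone 1 was 9.68 for Uba1y (a fitted value against 0 counts in clone 1, with at least 68.4-fold as its bound), 0.72 for Lama1, 1.83 for Atf5, -0.58 for Pdk1, 0.94 for Cdkn1a, which lies in the chromosome 17 stretch, -0.72 for Btg2, 1.47 for Peg10, -2.79 for Phlda2 and 1.36 for Peg3. Each was called against WT in both clones, in opposite directions, and the difference was tested directly. For Uba1y the call of clone 1 against WT rests on 6 counts in WT and 0 in clone 1, at least 1.94-fold higher in WT.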

How the results depend on the processing

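The alternative without the chromosome stretches and chromosome Y was chosen after the data were seen. No named gene or list with a call changed direction under any alternative. The genotype comparison gave 1752 genes with no filter beyond 1 count, 428 with a log2 fold of 1 or more and 3226 for the mean of the clone contrasts, which takes the difference between clones out of the spread, and 79 to 948 with 1 library left out. Clone 1 against WT gave 2163 by DESeq2, 1071 with a log2 fold of 1 or more and 1576 to 4310 with 1 library left out. Clone 2 against WT gave 1777, 878 and 1165 to 4191, and 4065 in a fit of the 4 libraries compared. Clone 2 against clone 1 gave 1358, 727 and 974 to 3155, and the shared genes were 869, 430 and 594 to 1990. With an estimated correlation 0 lists were called for genotype and 1 between the clones. A minimum fold lowers counts by construction, and for the other settings the cause was not tested. Where a group was left with 1 library, it was assumed to vary like the others. A replicate block gave 646, 4410, 3685, 3007 and 1964 genes for the 5 results in that order, and 6 and 11 lists; replicates share only a number, and deviations correlated at 0.0513 (WT and clone 1), -0.0125 (WT and clone 2) and 0.125 (clone 1 and clone 2). Without the stretches and chromosome Y the counts were 964, 3184, 2632, 2047 and 1317, and 6 and 11 lists. Counts not mentioned stayed within 1.5 times. Over all alternatives, named genes stayed on their side of the threshold in 1367 cases, lost a call in 186 and gained 1 in 93 for genotype, and in 1365, 129 and 14 between the clones. For lists these were 271, 9 and 8, and 232, 30 and 2. Depth limits calls of small changes and of genes with few counts.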

Other observations

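The test of X-linked genes was planned before its result was seen, and that of Y-linked reads was chosen afterwards.

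Gene groups beyond those described showed few calls for genotype. Cdkn2a rose by 3.18 ± 0.23 among 19 p53 targets and CDK inhibitors, where 1 rose, 1 fell and 17 were not called. With p adjusted over the list alone 2 rose and 1 fell, and the camera adjusted p was 0.877, with a median of -0.15 and a test direction of lower against a mean of 0.10. Imprinted genes had 2 rises, Mest by 1.56 ± 0.15 and H19 (adjusted p = 0.0327), and 2 falls, Grb10 by 1.42 ± 0.15 and Impact by 0.47 ± 0.10, among 21, and 3 and 3 adjusted over the list alone, with a camera adjusted p of 0.952, a median of 0.18 and a test direction of lower. Without WT replicate 1 or WT replicate 2 the calls of H19 and Impact were lost, with highest adjusted p over alternatives of 0.307 and 0.298, and H19 lost its call without clone 2 replicate 1 (0.0675) or clone 2 replicate 2 (0.0613) too. Neutral amino acid transport and mTORC1 sensing genes had 2 rises and 1 fall among 18 (3 and 2 adjusted over the list alone, camera adjusted p = 0.952). Glycolysis and hypoxia genes had 2 rises and 1 fall among 26 (9 and 1 adjusted over the list alone, camera adjusted p = 0.3).

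Wnt targets had 1 fall among 15 (2 adjusted over the list alone, camera adjusted p = 0.328), LIF and STAT3 targets 1 among 14 (1 and 0.952), interferon genes 1 among 9 (2 and 0.818) and cholesterol synthesis genes 0 among 20 (0 and 0.328). The medians of the Wnt, LIF and interferon lists were 0.05, 0.07 and 0.16, while their test directions were lower. Mitochondrially encoded genes had 0 calls among 12, with 2 lower adjusted over the list alone and a camera adjusted p of 0.0777, or 0.00972 without WT replicate 2 (range 0.00972 to 0.442). Between the clones, lists without a camera call were ERK and FGF targets (3 higher and 2 lower of 23, 0.876), Ras family and components (1 of 33 higher, 0.786), branched-chain amino acid catabolism (0 of 24, 0.786), core pluripotency factors (2 and 4 of 12, 0.487), mesoderm (4 of 10 lower, 0.135), trophoblast (2 and 2 of 10, 0.722), cell cycle (5 of 26 higher, 0.135), p53 targets (2 and 3 of 19, 0.693), Wnt targets (2 and 6 of 15, 0.165), interferon genes (2 of 9 lower, 0.449), mitochondrial genes (1 of 12 lower, 0.722) and extracellular matrix genes (4 and 6 of 22, 0.213). Of these, fry called cell cycle genes higher (adjusted p = 0.0460, range 0.0460 to 0.467) and extracellular matrix genes lower (0.0276, range 0.0276 to 0.467) in clone 2. For ERK targets the median was 0.02 and the mean -0.18, and for Ras components 0.04 and -0.01, with test directions of higher. Adjusted over the list alone, the higher and lower counts were 3 and 2, 0 and 0, 0 and 0, 2 and 4, 0 and 4, 3 and 2, 5 and 0, 2 and 3, 3 and 6, 1 and 2, 0 and 0, and 4 and 6.

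Genes higher in the libraries labelled knockout were 40 of 517 tested on X, or 7.74%, against 587 of 14009 on autosomes, or 4.19%, with Fisher's exact test p = 3.60e-04. X-linked genes may thus have risen more often, although neighbouring genes of 1 family are not independent.

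Counts from 5 Y-linked genes were 2725 in clone 2, 46 in WT and 9 in clone 1, so that WT stood at 1.56% of the clone 2 level after normalisation. The line is of male origin, and loss of Y in WT and clone 1, or a sample from another stock, may account for this; neither was tested. Reads assigned to the wrong library on a shared lane could give the few counts in WT and would affect the autosomal gene Wnt10b alike. In WT Wnt10b stood at 0.289% of its clone 2 level (Fisher's exact test p = 9.50e-05), while in clone 1 the order was turned, with 0.315% for the Y-linked genes and 0.672% for Wnt10b. That p covers counting error only, since reads are not independent molecules, and Wnt10b had 4 counts in WT, so wrongly assigned reads cannot be told apart from true expression. Pseudogenes annotated on Y were left out after their values were seen, because reads of Mid1-ps1 were abundant in WT. With Mid1-ps1, p was 7.81e-96.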
